A study of Homo sapiens with 10 samples.

How the data were processed

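Human prefrontal cortex DNA from 10 samples in 2 cohorts was enriched for 5hmC by selective chemical labelling and sequenced, per the labels' protocols. Samples were grouped by cohort and diagnosis as the labels give them. Bowtie and the genome build hg19 are named in the submitters' processing notes. Per the file headers, diffReps 1.55.4 counted reads, with a fragment size of 300 bp, in windows of 1000 bp moved in steps of 100 bp, tested Alzheimer's against control samples with a negative binomial test, kept windows with p under 0.0001 and merged overlapping ones into loci. Also per the file headers, no background libraries were used, and 397683 windows in cohort 1 and 300569 in cohort 2 entered the Benjamini-Hochberg adjustment.

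The signal values, per the file headers, are reads per locus divided by a normalization constant of each sample, given for every sample and as a group mean. The log2 fold changes and p-values are those of the authors' deposited tables. The constants were 1.29, 0.87 and 0.93 for the Alzheimer's samples and 0.89, 1.12 and 0.99 for the controls of cohort 1, and 0.95 and 0.61 against 1.33 and 1.27 in cohort 2. Multiplied by its constant, 100% of the values under 40 came within 0.1 of a whole number in each sample. Total library sizes were not used here. Depth is given as the constants and as the count mean in the headers, taken here as mean reads per bin, which ran from 2.28 to 6.49. Reads per listed locus are also given, but they hold the group difference that the loci were listed for and do not measure depth. Because the lists hold only loci that had already passed a threshold, every test on them is conditional on that selection and no share of the genome can be given.

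Loci on chromosomes 1 to 22 were used, and chromosome X entered an alternative. The counts of higher and lower loci were tested with exact two-sided binomial tests. Loci were called shared when they overlapped by at least 1 bp, and chance was estimated by moving all cohort 2 loci of a chromosome by a random circular offset 10000 times, with a one-sided permutation p. Replicate-level tests used limma 3.58.1 in R 4.3.3 on log2(value + 1) within each cohort, with a mean-variance trend and Benjamini-Hochberg adjustment over the number of windows in the headers, so its log2 changes understate those of low loci. The plan had named a count model for per-sample counts. The values were normalised and packed as text, and limma was used instead, a change made after the files were seen. A count model on values multiplied back by their constants was not run. The labels used here do not say how the samples relate to donors, and replicate-level p-values then measure only the spread between these samples. Tests that count loci or windows take those as units and hold no spread between samples. An exact test of 3 samples against 3 cannot go below p = 0.1. For depth, log2(value + 1) at each listed locus of cohort 1 was fitted on group by least squares with and without log2 depth. Other tests used Python 3.11.15 with SciPy 1.17.1 and statsmodels 0.14.6.

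Checked on simulated values with 200 changed loci among 7572, limma recovered 36.0% of 2-fold and 86.0% of 4-fold changes at the cohort 1 design, with 2 and 9 false calls. Among 2301 loci at the cohort 2 design it recovered 3.00% and 45.5%, with 0 false calls. These simulations were adjusted over the simulated loci alone. Most simulated loci were unchanged and none was selected for a group difference, so these rates do not describe the calls among the listed loci. In the overlap test on 2301 loci, planting 0, 20 and 40 overlaps gave excesses of 6.70, 24.8 and 41.7.

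The rule for named items was fixed before the data were examined: per cohort and direction the 6 genes with the most loci and the 4 loci with the smallest p, and across cohorts 10 shared in direction and 5 opposite with the most loci. No hg19 annotation was used here, so loci were named by coordinate. Reading "most loci" as 1 Mb windows, and for shared loci as the number of loci in the window around each, was a choice made after the files were seen. Genes shared between cohorts, gene lists and genomic location relative to genes were not analysed here. Genes per chromosome were counted from RefSeq names of another build and divided by the largest coordinate in the deposited tables. Alternatives fixed beforehand covered chromosome X, p under 0.01, absolute log2 fold changes of at least 1.5, runs of adjacent loci, mean counts of at least 10, the overlap criterion and each sample left out.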

Results

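5-Hydroxymethylcytosine (5hmC), the oxidation product of 5-methylcytosine made by TET enzymes and abundant in neurons, was mapped in human prefrontal cortex from people with Alzheimer's disease and from controls. DNA carrying the mark was captured by selective chemical labelling, in which a glucosyltransferase attaches an azide-bearing glucose to 5hmC and a biotin group is then clicked on for avidin purification. The 10 samples came from 2 brain collections, called cohort 1 (3 Alzheimer's and 3 control samples) and cohort 2 (2 and 2). For each cohort the authors deposited a list of differential loci, with a normalised read count of every sample at each locus, in hg19 coordinates. On chromosomes 1 to 22 the lists held 7572 loci in cohort 1 and 2301 in cohort 2. Median reads per listed locus were 36.9, 24.9 and 25.9 in the Alzheimer's samples and 16.9, 18.0 and 17.0 in the control samples of cohort 1. In cohort 2 they were 14.98 and 9.96 in the Alzheimer's samples and 6.98 and 6.99 in the controls. These medians hold the group difference that the loci were listed for and do not measure depth. The count means of the file headers in cohort 2 were 3.56 and 2.28 in the Alzheimer's samples and 4.78 and 4.5 in the controls.

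The first comparison asked where 5hmC differed between Alzheimer's and control cortex in cohort 1. Of the 7572 loci, 5412 (71.5%) were higher and 2160 were lower in Alzheimer's disease. The median log2 fold change in the authors' deposited table was 1.17 at the higher loci (quartiles 1.02 and 1.34) and -0.94 at the lower loci (quartiles -1.15 and -0.79). The higher loci were most crowded in a few regions. Chromosome 9 held 54 of them between 138000001 and 139000000 and 49 in the megabase before it, chromosome 20 held 49 between 61000001 and 62000000, and chromosome 10 held 43 between 132000001 and 133000000. Chromosome 14 (101000001 to 102000000) and chromosome 22 (48000001 to 49000000) held 42 each. In the chromosome 10 and chromosome 14 regions no listed locus was lower, and in the other 4 regions between 1 and 4 were.

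Loci with less 5hmC in cohort 1 were most crowded on chromosome 19, between 1000001 and 2000000, where 24 were lower and 4 higher. Next came chromosome 2 between 240000001 and 241000000 with 19 lower and 4 higher loci, and the first megabase of chromosome 16 with 18 lower and 5 higher. On chromosome 1, 17 loci were lower and 3 higher in the megabase starting at 1000001, and 17 lower and 9 higher in that starting at 2000001. The second megabase of chromosome 16 held 16 lower and 15 higher loci.

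At the named loci the groups lay further apart than the spread between samples. These loci were chosen for the smallest p of this same contrast, so their separation and limma p-values are no independent support. The limma fit also estimated its spread from the listed loci alone. The higher locus with the smallest p in the authors' deposited table, chromosome 2 from 127859901 to 127863000, had 90.4 ± 8.71 normalised reads in Alzheimer's disease and 29.3 ± 8.76 in controls (SD, n = 3 each). Its limma log2 change was 1.63 ± 0.19 (SE), with an adjusted p of 8.5e-06. Chromosome 9 from 116298001 to 116301300 had 83.6 ± 2.02 against 29.2 ± 7.11, chromosome 12 from 130930501 to 130933300 had 94.5 ± 7.23 against 41.4 ± 2.81, and chromosome 5 from 2258601 to 2261800 had 85.9 ± 3.85 against 36.1 ± 5.78. Among lower loci, chromosome 1 from 156593001 to 156595900 had 46.9 ± 4.66 in Alzheimer's disease against 113 ± 5.51 in controls, a limma log2 change of -1.25 ± 0.16 with an adjusted p of 2.9e-05. Chromosome 11 from 1320001 to 1322000 had 44.7 ± 5.91 against 97.9 ± 8.57, chromosome 2 from 25473401 to 25475800 had 47.8 ± 8.76 against 106 ± 4.16, and chromosome 15 from 102036801 to 102038700 had 66.2 ± 8.33 against 109 ± 6.16.

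The excess of higher loci in cohort 1 passed an exact two-sided binomial test against an even split (p = 1.4e-315). Neighbouring loci are not independent, though, and the test holds no spread between samples. Scaling samples to the count means of the file headers, a setting chosen after the data were seen, shifted the cohort 1 loci by a median of -0.24 on the log2 scale. It changed the sign of 0 loci, which was in effect fixed in advance, since the smallest change of a higher locus was 0.4. The share of higher loci among those at or over an absolute log2 of 1.5 went from 79.4% to 21.2%, as a shift against a fixed limit can do. All 3 Alzheimer's samples lay beyond all 3 controls at 7559 loci (99.8%, where chance gives 10%), and limma called 7524, but the loci had been selected for this difference. Of these calls 5401 were higher and 2123 lower. With each sample left out in turn, limma called 3155 to 5321 higher and 809 to 1967 lower loci.

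Direction in cohort 1 went with signal. Loci with a mean normalised count of 10 to 20 were higher in 84.5% of cases, those of 30 to 50 in 64.0%, those of 50 to 100 in 36.0% and those over 100 in 12.8%. The 8 loci with a count under 10 were all lower. The median of the mean count over both groups was 21.7 normalised reads at the higher loci and 33.7 at the lower loci. Across loci, which are not independent replicates, Spearman's rho between signal per kb and being higher was -0.35 (permutation p = 1.0e-05, the smallest the permutations can give). Among loci with an absolute log2 fold change of at least 1.5, rho was 0.23.

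**Figure D1:**
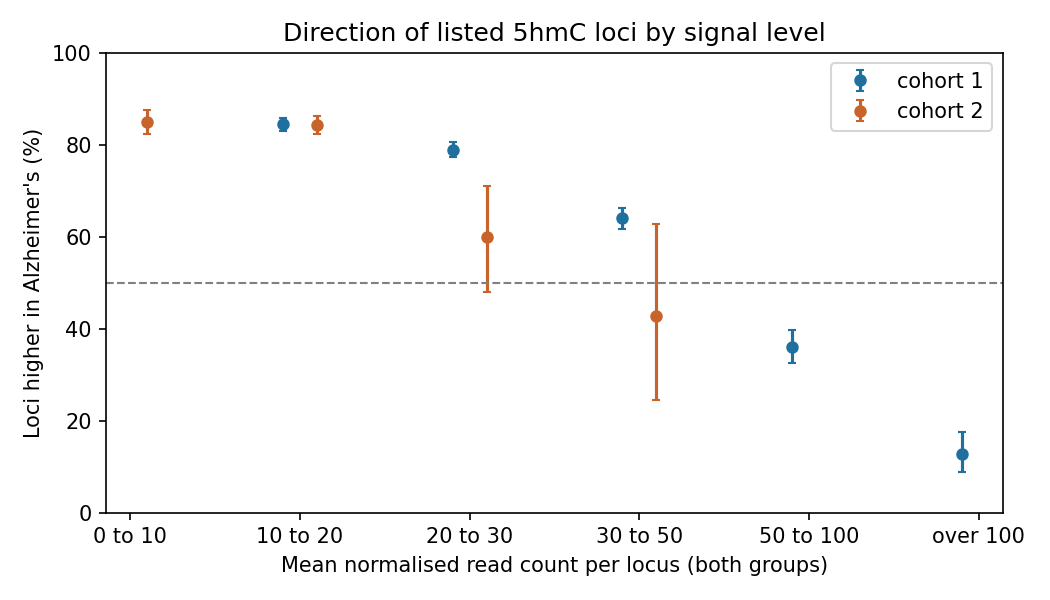
Percentage of listed loci that were higher in Alzheimer's disease (y axis) by class of mean normalised read count per locus (x axis), with exact 95% intervals that treat loci as independent. In cohort 1 the percentage fell from 84.5 at counts of 10 to 20 to 12.8 at counts over 100, and classes of fewer than 20 loci are not drawn.

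Chromosome 19 stood apart in cohort 1. Of its 291 listed loci 87 (29.9%) were higher in Alzheimer's disease, against 73.1% on the other chromosomes, with an odds ratio of 0.157 (Fisher's exact test, two-sided, p = 8.0e-51, 3.5e-49 after adjustment over 44 tests). Among loci with an absolute log2 fold change of at least 1.5 the odds ratio was 0.661, which did not pass (Fisher's exact test, p = 0.525). Chromosome 17 also had fewer higher loci (63.2%), and chromosomes 10, 14 and 20 had more (78.9%, 79.2% and 79.8%; adjusted exact p = 0.0023, 0.0031, 0.0442 and 0.0040 in this order). In cohort 2, 150 of 168 loci on chromosome 19 were higher (89.3%, against 82.6% elsewhere), which did not pass after adjustment (exact p = 0.0247, adjusted 0.0989). The difference between the cohorts' odds ratios passed Zelen's exact test (two-sided p = 3.1e-22, and 1.2e-09 with 1 Mb windows counted once by majority). Loci and windows, not samples, are the units of these tests.

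**Figure D2:**
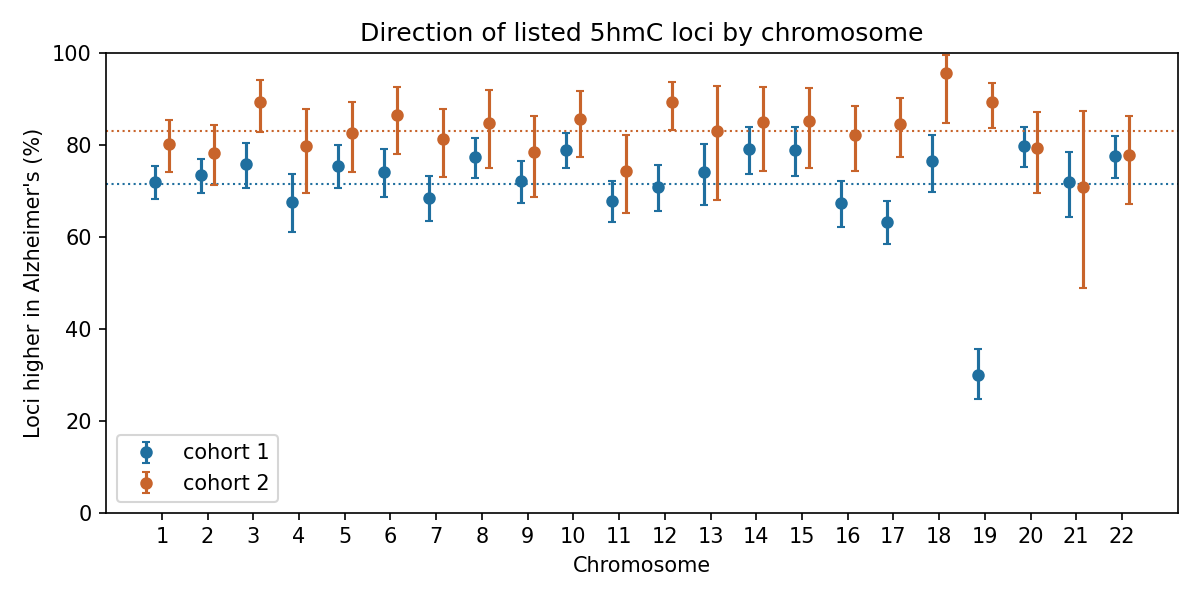
Percentage of listed loci that were higher in Alzheimer's disease (y axis) on chromosomes 1 to 22 (x axis), with exact 95% intervals that treat loci as independent; dotted lines mark each cohort's total, 71.5% and 83.1%. Chromosome 19 of cohort 1, at 29.9%, lies below all other chromosomes of both cohorts.

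The second comparison asked the same question in cohort 2. Of 2301 loci, 1912 (83.1%) were higher and 389 lower in Alzheimer's disease, and the median log2 fold change in the authors' deposited table was 2.00 for higher loci (quartiles 1.76 and 2.17) and -2.05 for lower loci (quartiles -2.42 and -1.71). By single megabase, higher loci were most crowded on chromosome 19, in those starting at 12000001 (10 loci), 19000001 (9), 45000001 (9) and 3000001 (8). As a whole, chromosome 1 held more higher loci than chromosome 19 (170 against 150). Chromosome 3 from 47000001 to 48000000 and chromosome 7 from 100000001 to 101000000 also held 8 each, with no lower locus. Lower loci were most numerous on chromosome 4 from 1000001 to 2000000, with 5 beside 2 higher ones. The megabases starting at 61000001 on chromosome 20, at 109000001 on chromosome 2 and at 228000001 and 1000001 on chromosome 1 held 4 each, as did the first megabase of chromosome 16. In these 5 regions between 0 and 4 loci were higher, and the region from 1000001 on chromosome 1 was evenly split with 4 of each.

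The higher locus of cohort 2 with the smallest p in the authors' deposited table was chromosome 15 from 75884701 to 75886800, with 41.5 ± 6.26 normalised reads in Alzheimer's disease and 11.2 ± 4.16 in controls (SD, n = 2 each). Chromosome 19 from 36996701 to 36998700 had 28.0 ± 2.16 against 5.70 ± 3.62, chromosome 19 from 2152601 to 2154600 had 34.1 ± 0.389 against 8.85 ± 0.827, and chromosome 10 from 74344101 to 74345900 had 26.3 ± 0.163 against 5.39 ± 1.26. Among lower loci, chromosome 21 from 32307001 to 32308700 had 3.23 ± 0.0778 against 22.3 ± 2.88, and chromosome 11 from 71068101 to 71069500 had 3.46 ± 2.58 against 23.01 ± 1.43. A mean of 3.23 stands for only a few reads per sample, so the SD of 0.0778 does not measure how well samples agree. Chromosome 7 from 16437801 to 16440400 had 53.5 ± 20.1 against 139 ± 4.78, and chromosome 21 from 9824701 to 9827100 had 127 ± 19.6 against 232 ± 0.679.

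The higher loci of cohort 2 had a median control signal of 3.86 normalised reads per kb, 1.06 times the mean of 1 kb bins (the count mean of the headers divided by each sample's constant), against 2.38 times for the higher loci of cohort 1; a low control signal is in part fixed by choosing loci that were higher. The excess of higher loci had an exact two-sided binomial p of 1.4e-240, which holds no spread between samples. With 2 samples per group limma called 0 of the 2301 loci after Benjamini-Hochberg adjustment over 300569 windows, 2301 had an unadjusted p under 0.05, and with a pseudocount of 5 instead of 1 it called 1897 higher and 385 lower.

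The third comparison asked whether the 2 cohorts pointed to the same loci. Only 33 loci overlapped, 0.436% of the cohort 1 list and 1.43% of the cohort 2 list. Loci lower in both cohorts made up the largest share, 13, where shifting cohort 2 along its chromosomes gave 0.89 on average (permutation p = 1.0e-04, the smallest the shifts can give, and 4.0e-04 after adjustment over 4 direction pairs). Loci higher in both cohorts numbered 6, against 9.60 by chance (adjusted p = 0.907). A further 8 were higher in cohort 1 and lower in cohort 2, against 2.01 by chance (adjusted p = 0.0032), but shifts of 20 to 200 kb gave 7.19 (permutation p = 0.432). Another 6 were lower in cohort 1 and higher in cohort 2, against 4.83 by whole-chromosome shifts (adjusted p = 0.468). Of the cohort 2 loci, 21 of 389 lower ones (5.40%) and 12 of 1912 higher ones (0.628%) overlapped a cohort 1 locus, an odds ratio of 8.87 (Fisher's exact test, two-sided, p = 1.9e-09). Shifts of 20 to 200 kb alone gave a median odds ratio of 3.06 (one-sided permutation p = 0.0036). Neither kind of shift matched loci on signal. The median control signal of lower loci was 7.72 times the mean of 1 kb bins in cohort 1 and 5.24 times in cohort 2. For higher loci it was 2.38 and 1.06 times. This contrast is in part fixed by choosing loci for their direction. In the Alzheimer's samples, the median signal of higher loci was 5.36 times that mean in cohort 1 and 4.34 times in cohort 2. Because the shifts were not matched on signal, an overlap of strong sites cannot be told apart here from a shared loss.

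**Figure D3:**
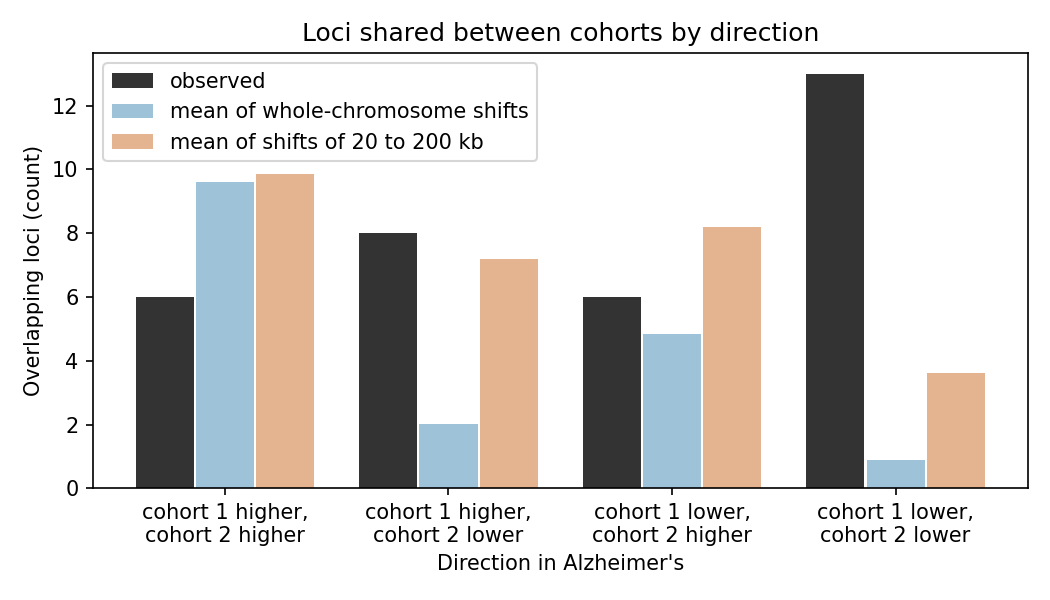
Number of overlapping loci (y axis) for each pair of directions in the cohorts (x axis): observed counts, the mean of 10000 shifts of cohort 2 along whole chromosomes, and the mean of shifts of 20 to 200 kb. The 13 loci lower in both cohorts stand above both chance means, 0.89 and 3.62, neither of which is matched on signal. An even spread over the tested windows, not drawn, would give 6.76.

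Shared loci had a higher signal than the lists they came from, with a median of 46.5 normalised reads against 23.7 for all loci in cohort 1 and 16.1 against 11.3 in cohort 2, which was not tested. Values are those of each cohort's own locus, which reaches beyond the overlap in most cases. On chromosome 1, the cohort 1 locus from 1264301 to 1266200 had 385 ± 31.5 normalised reads in Alzheimer's disease against 526 ± 34.3 in controls (n = 3 each), and the cohort 2 locus from 1265101 to 1266100 had 28.4 ± 3.15 against 59.6 ± 4.63 (n = 2 each). On chromosome 17, the cohort 1 locus from 80617301 to 80619000 had 310 ± 17.8 against 455 ± 77.2, and the cohort 2 locus from 80617101 to 80618100 had 16.7 ± 0.382 against 44.2 ± 3.05. On chromosome 13, the cohort 1 locus from 114749001 to 114750100 had 211 ± 35.2 against 288 ± 7.05, and the cohort 2 locus from 114748901 to 114750300 had 34.6 ± 0.354 against 63.7 ± 3.38. The other overlaps of loci lower in both cohorts that the rule named began on chromosome 10 at 134579301, chromosome 17 at 72353401, chromosome 19 at 5081001, chromosome 9 at 131669101, and chromosome 4 at 880901 and at 1019201. Of the 13 loci lower in both cohorts, limma called 9 in cohort 1 and 0 in cohort 2. The 4 not called in cohort 1 were those on chromosomes 1 and 13 given above (limma adjusted p = 0.0754 and 0.128) and both on chromosome 4 (1 and 0.653). Of the 6 loci higher in both cohorts, the rule named only one overlap on chromosome 7. There the cohort 1 locus from 100549401 to 100552000 had 104 ± 10.2 against 51.0 ± 13.8. The cohort 2 locus from 100548501 to 100549500 had 20.9 ± 1.80 against 7.29 ± 0.311, with an overlap of 100 bp. The others lay on chromosomes 2, 7, 8, 14 and 19. Levels were normalised separately in each cohort and are not comparable between them.

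The named loci with opposite changes were higher in cohort 1 and lower in cohort 2. On chromosome 9, the cohort 1 locus from 137711901 to 137714800 had 147 ± 14.4 in Alzheimer's disease against 76.6 ± 14.5 in controls, and the cohort 2 locus inside it, from 137712401 to 137713400, had 8.04 ± 2.10 against 25.8 ± 3.54. The other overlaps began on chromosome 7 at 157291701, chromosome 8 at 142645301 and at 1467701, and chromosome 5 at 1963301.

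Across the 33 shared loci, 19 (57.6%, exact 95% interval 39.2 to 74.5) had the same direction, which did not differ from an even split (exact two-sided binomial p = 0.487), and the cohorts' shares of higher loci alone give 64.2%. The total of 33 exceeded the 17.3 of whole-chromosome shifts (permutation p = 0.0012) but not the 28.9 of shifts of 20 to 200 kb (p = 0.238), and an even spread over the windows tested in cohort 2 would give 140. The 13 loci lower in both exceeded the 3.62 of the short shifts (permutation p = 2.0e-04), which are not matched on signal. The even spread would give 6.76, a difference that was not tested. The 8 loci higher in cohort 1 and lower in cohort 2 did not exceed the 7.19 of the short shifts (permutation p = 0.432), and the even spread would give 16.5. Fold changes in the authors' deposited table did not go together across the 33 loci, which are not independent replicates (Pearson's r = -0.18, permutation p = 0.323, and -0.20 without the 2 loci farthest from the median; Spearman's rho = -0.27, permutation p = 0.125; 1 relation).

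**Figure D4:**
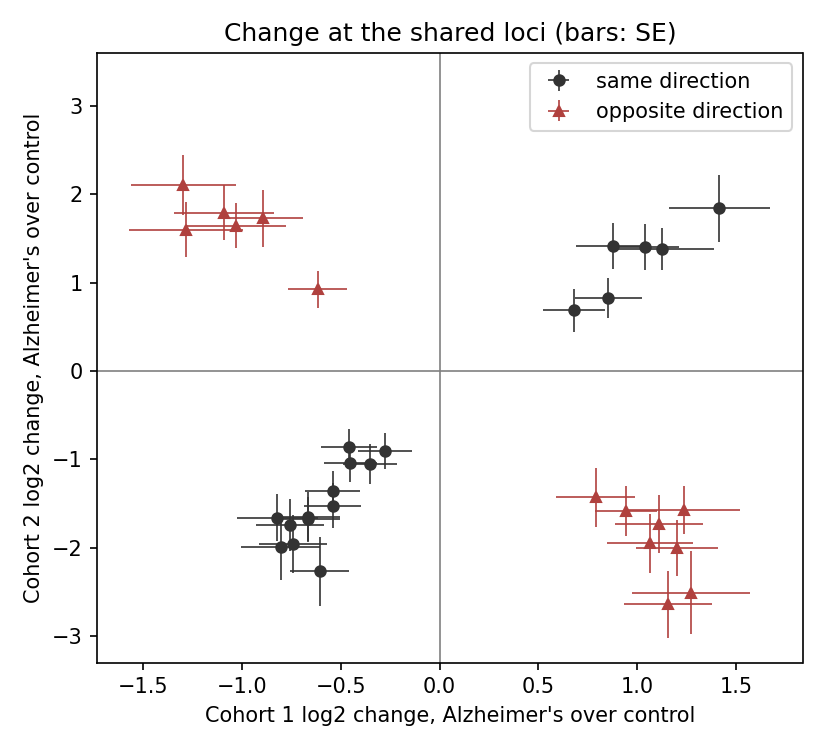
limma log2 change in cohort 1 (x axis) and cohort 2 (y axis) at the 33 shared loci, with standard errors. The 19 loci with the same direction lie at the lower left and upper right, and the 14 with opposite directions at the upper left and lower right.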

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

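The tests on excess variance, depth, regions of chromosome 19, gene density and fold size, and both comparisons between cohorts, were chosen after the results were seen. Those on the authors' normalization, on signal level at chromosome 19 and on other splits were written down before their values were seen.

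Chromosome 19 went opposite ways in the cohorts. In cohort 1, 87 of its 291 loci (29.9%) were higher in Alzheimer's disease, against 73.1% on the other chromosomes (odds ratio 0.157, 95% interval 0.122 to 0.203, Fisher's exact test, two-sided, p = 8.0e-51). In cohort 2, 150 of 168 (89.3%) were higher, against 82.6% elsewhere (odds ratio 1.72, exact p = 0.0247, 0.0989 after adjustment over both cohorts' chromosomes). The ratio of the odds ratios was 0.0917 (Zelen's exact test, two-sided, p = 3.1e-22, and 1.2e-09 with 1 Mb windows counted once by majority). These tests count loci or windows and hold no spread between samples. Among cohort 1 loci with an absolute log2 fold change of at least 1.5 the odds ratio was 0.661 (exact p = 0.525).

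For chromosome 19, the level of its loci is argued against as the whole cause by an odds ratio of 0.188 (95% interval 0.140 to 0.254) within 10 classes of signal in cohort 1. One region of the chromosome is argued against by 8 of 9 windows of 5 Mb with 10 or more loci having mostly lower loci. The pattern was not uniform, however. The exception, from 30 to 35 Mb, had 24 higher and 14 lower loci. Of the windows with fewer loci, that from 25 to 30 Mb had 8 of 9 higher and that from 40 to 45 Mb had 4 of 9. A bias with gene density may contribute and stays open: over the other 21 chromosomes of cohort 1, Spearman's rho between genes per Mb and the share of higher loci was -0.22 (permutation p = 0.338) and Pearson's r was -0.47 (p = 0.0287, 0.0382 after adjustment over 12 relations), falling to -0.06 without the 2 chromosomes farthest from the median. GC content was not analysed here. A difference between cohorts in the donors or in the disease stays open and untested.

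More loci were higher than lower, most of all at low signal over the full lists. In cohort 1 the 8 loci with a mean count under 10 were all lower, however. Among cohort 1 loci with an absolute log2 fold change of at least 1.5, rho of signal with direction was 0.23. Unequal depth stays open in cohort 1. The groups' constants overlapped (0.87 to 1.29 against 0.89 to 1.12), while the mean of the headers' count means was 1.23 times higher in Alzheimer's disease. With those count means as a covariate the higher loci kept 102.8% of their median log2 change (1.16 against 1.13). Over both directions, both measures of depth and leaving out each sample, 86.0% to 106.4% was kept. The loci were listed for this group difference and depths overlapped between groups, so little could be lost and the fit cannot decide. Whether depth had a part in which loci were listed, and so in the excess of higher ones, was not tested. In cohort 2 depth cannot be told apart from diagnosis, since the constants differed by a ratio of 0.60 and did not overlap. A weaker capture contrast in the Alzheimer's libraries of cohort 1 stays open. Excess variance of bin counts, Alzheimer's minus control, differed by -0.0721 (exact permutation p = 0.4), in the direction that a weaker contrast predicts, with few samples. The groups overlapped (0.9085, 0.9932 and 1.093 against 1.02, 1.135 and 1.056). The prediction that all 3 Alzheimer's libraries lie below all 3 controls was thus not met. The signal at which lost contrast would change direction is not known. The authors' normalization stays open in cohort 1: after scaling to the headers' count means, which were 1.19 times higher in Alzheimer's disease once divided by the constants, 21.2% (95% interval 17.7 to 25.0) of loci at or over a log2 of 1.5 were higher. That met the bound set before this value was seen, though the scaling itself was chosen after the data were seen. A shift against a fixed limit can do this by itself, so meeting the bound cannot decide. That 0 loci changed sign, with 71.5% of all listed loci still higher, cannot weigh against the normalization as a cause. The smallest change of a higher locus was 0.4, beyond the size of the median shift of -0.24. The lists were made under the authors' scale, and a genome-wide gain of 5hmC was not tested.

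Few loci were shared between the cohorts. If cohort 2 had missed all but large changes, large cohort 1 changes would overlap more often in the same direction; 0 of 654 loci with an absolute log2 fold change of at least 1.5 and 19 of 6918 others did (odds ratio 0.270, 95% interval 0.0163 to 4.48, exact p = 0.402), too few to decide. At 14 shared loci the cohorts had opposite directions, with every Alzheimer's sample beyond every control in both, as at 99.8% of all listed loci of cohort 1 and 100% of those of cohort 2 through their selection, and these differences were not tested.

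Near distal chromosome ends the cohorts also differed: within 5 Mb of the largest listed coordinate lay 22.7% of higher and 16.3% of lower loci in cohort 1, and 4.97% and 21.1% in cohort 2, a ratio of odds ratios of 7.67 (Zelen's exact test, two-sided, p = 1.4e-28; 9.63 with 1 Mb windows counted once by majority, p = 4.6e-11). Within 2 Mb the odds ratio of cohort 1 was 0.936 (Fisher's exact test, p = 0.470). Only the end with the largest coordinate was counted, so loci near the start of a chromosome counted as not distal. Some of the regions most crowded with lower loci lay there. The first megabase of chromosome 16 held 18 lower loci in cohort 1 and 4 in cohort 2. The values thus do not describe both ends of a chromosome. Here too loci or windows, not samples, were the units.

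Of the 10 splits of the 6 cohort 1 samples, 1, the real one, gave 7524 limma calls, and the highest of the others gave 0. The splits are too few for a share under 0.05, and the loci had been selected on the real split.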

How the results depend on the processing

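Of 205 recomputed values, 177 kept their direction and side of the threshold or stayed within their spread or 1.5 times the count; the cause of the other changes was not tested unless stated. At an absolute log2 fold change of at least 1.5, cohort 1 had 519 higher and 135 lower loci with medians of 1.59 and -1.59 (fewer loci by construction), the chromosome 19 odds ratio of cohort 1 was 0.661, rho of signal with direction in cohort 1 was 0.227, and 0 loci were shared. With a mean count of at least 10, cohort 2 had 1256 higher loci, its chromosome 19 odds ratio was 1.66 (exact p = 0.0699), and limma called 1246 higher and 272 lower loci there, against 0 and 0. limma called 1897 higher and 385 lower cohort 2 loci with a pseudocount of 5, and 1912 and 389 when adjusted over the listed loci alone. Within 10 kb, 47.3% of shared loci had the same direction (exact p = 0.400). With shifts of 20 to 200 kb the 33 shared loci were not beyond chance (permutation p = 0.238), and an even spread over the tested windows would give 139.7. Scaled to the count mean of the headers, 21.2% of cohort 1 loci at or over a log2 of 1.5 were higher, against 79.4%, because a median shift of -0.24 moved loci over a fixed limit. The smallest change of a higher locus was larger, 0.4, so that 0 loci changed sign was in effect fixed in advance. Cohort 2 went from 83.9% to 83.0%. At 2 Mb the distal odds ratio of cohort 1 was 0.936. Leaving out each sample in turn, limma called 3155 to 5321 higher and 809 to 1967 lower loci in cohort 1, and 0 to 797 higher and 0 to 389 lower loci in cohort 2, where a lone sample is assumed to vary like the other group. The higher count of cohort 1 moved by over 1.5 times without Alzheimer's replicate 1 (3189), 2 (3155) or 3 (3563), the lower count without control replicate 3 (809), and both counts of cohort 2 without Alzheimer's replicate 1 (797 and 376) or 2 (613 and 389). Settings chosen after seeing the data were the pseudocounts, the adjustment, the shifts, the even spread, the scaling, the distal and neighbour distances, the submitters' adjusted p and 1 Mb windows. The count models, with or without their own low-count filter, and the gene and location alternatives were not run. No paired analysis was possible because the labels give no shared replicate numbers. With the samples, loci and depth of cohort 2, 3.00% of simulated 2-fold changes were recovered among loci not selected for a difference. Depth alone was not varied.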

Other observations

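Neighbouring listed loci had the same direction more often than chance gives, at distances that differed between the cohorts. In cohort 1, 92.5% of 1423 neighbouring pairs less than 10 kb apart had the same direction, 82.4% of 3078 pairs 10 to 100 kb apart, and 63.3% of 2452 pairs 100 to 1000 kb apart, where permuting directions within chromosomes gave 61.0%, 60.9% and 60.8%. In cohort 2 the shares were 89.9% of 79, 81.7% of 389 and 76.3% of 1146 pairs, against 72.7%, 72.6% and 72.1%. The permutation p-values for neighbours are one-sided and test for an excess. Beyond 1000 kb the share in cohort 1 was 55.0% against 60.8% (permutation p = 0.999). Nearly all permutations thus gave a share at least as high, and a deficit was not tested. In cohort 2 the share was 77.4% against 71.8% (permutation p = 1.0e-03), so its excess was not particular to close loci. At the shorter distances the permutation p was 1.0e-03, the smallest that 1000 permutations can give, except at 100 to 1000 kb in cohort 1 (p = 0.0050).

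Lower loci of both cohorts and higher loci of cohort 2 were denser on gene-rich chromosomes, while for the higher loci of cohort 1 neither correlation passed after adjustment unless chromosome 19 was left out (Spearman's rho 0.55, permutation p adjusted 0.0182; Pearson's r 0.59, permutation p adjusted 0.0129). Over 22 chromosomes, Spearman's rho between genes per Mb and loci per Mb was 0.44 for higher and 0.73 for lower loci of cohort 1 (permutation p adjusted over 12 relations 0.0653 and 5.0e-04), and 0.86 and 0.78 for those of cohort 2 (6.0e-05 and 2.4e-04). Pearson's r was 0.21, 0.96, 0.95 and 0.71 (adjusted p = 0.370, 4.0e-05, 4.0e-05 and 2.8e-04), and 0.58, 0.75, 0.79 and 0.81 without the 2 chromosomes farthest from the median. These relations were chosen after the data were seen.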
